A study of Mus musculus with 4 samples.

How the data were processed

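The deposited matrices hold UMI counts per gene and barcode, made per the file headers with Cell Ranger 6.1.0, while the submitters' notes name version 7. Libraries were 10x 3-prime version 3.1, read with 150 bases on a NovaSeq 6000. Each sample has a second matrix, left out because its entries were identical. The files hold 32285 genes, and 99.6% of their identifiers were found in GENCODE release 21 for mouse (mm10). No read was realigned, and no replicate exists.

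Cells were kept with at least 500 UMIs, 300 genes and under 15% mitochondrial UMIs. Doublets were removed by a score from 2 simulated doublets per cell. Cells of all libraries were clustered together on 3000 variable genes, 30 components and 20 neighbours with Leiden at resolution 1, which gave 27 clusters and 14 T cell sub-clusters. Clusters were named from 174 marker genes, with at least 3 markers each detected in 25% of cells and 2-fold higher than in other clusters. A cluster with over 1 Y-linked UMI per 10000, and more of these than of Xist, could not take the name of a host class. This rule and the naming thresholds were set after the data were seen. Lists, comparisons, filters and the first set of alternatives were fixed before the data were examined.

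Levels are CPM, the summed UMIs of a gene scaled to those of its class in a library, with exact 95% Poisson intervals. Folds and log2 ratios add 0.5 counts to each sum, and a gene with 0 UMIs is given as a bound against a floor of 3 counts. Shares carry exact binomial intervals. A list was summed up by the median log2 ratio of members with at least 20 UMIs, in classes of at least 50 cells per library, apart from endothelial-like cells of the combination. List intervals came from 1000 Poisson redraws, and percentiles from 10000 random lists matched on expression. Members at least 1.5-fold apart are counts of size, not of tests.

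The 22 lists, written from general knowledge, were type I interferon response, interferon-gamma response, MHC class I presentation, MHC class II presentation, cytosolic nucleic acid sensing, p53 targets, DNA repair and PARP, proliferation, cytotoxic effector, inhibitory receptors and exhaustion, naive and memory T cell, T cell-recruiting chemokines, neutrophil chemoattractants, immunosuppressive macrophage, inflammatory macrophage, matrix and myofibroblast, inflammatory fibroblast, epithelial to mesenchymal transition, hypoxia, dissociation stress, Y-linked, and X inactivation. Of their 382 genes, 8 were not in the files.

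Genes were named by a fixed rule. It took the 3 highest and 3 lowest log2 ratios per comparison in tumour-like, macrophage, T and fibroblast-like cells, among genes with at least 100 UMIs and intervals that did not overlap, without markers of other classes or genes higher in another common class. It added up to 4 members with the most UMIs of each list, and 16 genes always named, among them Isg15, Ifit1, Cxcl10, Gzmb and Cdkn1a. Genes that name a cluster are those leading over all other clusters.

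The comparison of summed counts was tested on simulated data with known differences, for tumour, macrophage and T cell-like classes only, where 93 to 100% of genes set 2-fold apart and 100% of those set 4-fold apart were recovered. Counts were drawn as Poisson around class means, the same error that the intervals assume. Clustering, naming and variation between cells or animals were not simulated, so these rates cover counting error only. Of unchanged genes 0.477 to 4.13% had intervals apart, and unchanged lists had an interval holding 0 in 96 to 100% of draws. Alternatives tried were a stricter filter (1000 UMIs, 500 genes, 10%), every barcode, doublets kept, resolution 2, each library clustered alone, classes from UMIs per cell, median-ratio scaling, members with at least 100 or 1 UMIs, 5 CPM added, and the mean over cells. Leaving out B cell-like and naive T cells, or the tumour-like cluster of few UMIs, was added later. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.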

Results

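Single-cell RNA was counted in 4 libraries of subcutaneous tumours grown from mT4 cells, a mouse pancreatic cancer line, in female C57/Bl6 mice. The labels give 1 library each for control IgG, radiation (RT), RT with an antibody that blocks PD-L1, and RT with that antibody and olaparib, an inhibitor of PARP enzymes; the last is called the combination library here. Each library pooled 6 to 8 tumours taken on day 5, counted from the day of the 1 dose of 8 Gy in irradiated groups, and none has a replicate, so no test between groups was possible and every interval covers counting error only. The study asks, in its title, whether olaparib and radiation raise type I interferon and make tumours respond to immunotherapy through CD8 T cells. The protocol text names AZD1390, an ATM inhibitor, at 20 mg/kg where the sample labels name olaparib, and lists a group on AZD1390 alone where the sample labels name RT. No dose of olaparib is given. Groups are named here by the sample labels, so what the combination library adds to RT and anti-PD-L1, and what the RT library received, rest on those labels.

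The libraries held 5323 barcodes and 66792216 UMIs (unique molecule counts) in control, 5402 and 61900092 in RT, 6183 and 81481022 in RT+anti-PD-L1, and 5755 and 99697462 in the combination. After filtering, 4622, 4518, 5339 and 5041 cells were kept in the same order, with a median of 4445.5, 4601.5, 6057 and 7475 UMIs per cell. Levels are given as CPM, the UMIs of a gene scaled to the summed UMIs of its class. Tumour-like cells carried 165 CPM of Y-linked genes and 5.08 CPM of Xist, the RNA of the inactive X chromosome, while host classes carried at most 7.40 and at least 436 CPM. Sex-linked RNA thus set the line apart from its female hosts. It was also used in naming the clusters, so it is not separate support for the classes. Within each class the median log2 ratio over all genes stayed within 0.1 of 0, apart from neutrophil-like cells of the combination against RT+anti-PD-L1 (-0.10). Because CD45-positive and CD45-negative cells were remixed in equal parts, immune shares are given among immune cells and stromal shares among non-immune cells.

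Against control, the RT library addressed what radiation alone does, and its clearest contrast lay in resting lymphocytes. Naive T cell-like sub-clusters, marked by Lef1, Ccr7 and Dapl1, made up 20.2% of immune cells in control (95% interval 18.9 to 21.6) and 3.78% in RT (3.14 to 4.52). B cell-like cells made up 11.6% (10.5 to 12.7) in control and 1.40% (1.02 to 1.88) in RT, 8.16-fold less. NK cell-like cells were 2.90-fold more frequent in RT (8.74%, 7.76 to 9.79, against 3.00%, 2.45 to 3.64), monocyte or macrophage-like cells 1.60-fold (19.1% against 11.9%) and neutrophil-like cells also 1.60-fold (18.7% against 11.7%). Among immune cells without B cell-like and naive T cells these folds were smaller, at 2.09 for NK cell-like cells and 1.15 for each of the others. T cell-like cells took 48.1% (46.3 to 49.8) of immune cells in RT and 58.7% (57.0 to 60.4) in control, a log2 ratio of -0.29. CD8 T cell-like cells took 16.8% (15.5 to 18.2) in RT and 20.7% (19.3 to 22.1) in control, a log2 ratio of -0.30 (-0.45 to -0.15). This difference turned when B cell-like and naive T cells were left out, to 16.5% against 16.0% (log2 ratio 0.05), and when doublets were kept (0.54).

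In tumour-like cells the type I interferon response list, genes switched on by interferon-alpha and -beta, had a median log2 ratio of 0.30 (0.23 to 0.32) in RT against control, with 5 of 38 measured members at least 1.5-fold higher and 0 lower. Isg15, a ubiquitin-like antiviral protein, stood at 87.2 CPM (84.4 to 90.0) in RT and 77.9 (75.4 to 80.5) in control, and Ifit1, a sensor of viral RNA, at 31.5 and 30.8. T cell-attracting chemokines were further apart. Cxcl9 was 1.39-fold and Cxcl10 1.40-fold higher in RT, and 4 of 9 measured chemokines of this kind were at least 1.5-fold higher. H2-K1 and H2-D1, heavy chains of MHC class I, were each 1.32-fold lower, and that list had a median of -0.16 (-0.22 to -0.13). Cdkn1a, the cell cycle inhibitor p21, was 1.84-fold higher in RT at 17.5 CPM (16.3 to 18.8), although the list of p53 targets had a median of only 0.05 (-0.02 to 0.15). Mki67, a mark of dividing cells, differed by 1.06-fold. The dissociation stress list, which rises during tissue digestion, was also higher in RT tumour-like cells, with a median of 0.19 and Fos 1.44-fold higher. Among genes chosen by the size of their difference, Agr2, a mucous secretory gene, was 4.64-fold lower in RT, with 60.7% of its control UMIs in 5 cells. Nts, the neurotensin precursor, was 6.39-fold lower, and Defb48, a defensin, at least 58.2-fold higher, yet 5 cells held 98.9% and 100% of their UMIs.

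Macrophages differed more in antigen presentation than in interferon genes. All 9 MHC class II genes were at least 1.5-fold lower in RT, with a list median of -1.09 (-1.20 to -1.04), and H2-Ab1 stood at 1613 CPM (1570 to 1657) against 3679 (3596 to 3764) in control. The clusters differed too, since the C1q-rich cluster held 64.1% of these cells in control and 41.3% in RT, while the Arg1-rich cluster held 16.8% and 31.2%. Retnla, a product of alternatively activated macrophages, was 7.69-fold lower, with control UMIs in 41 of 393 cells. Ccl17, a chemokine for Th2 cells, was 7.07-fold lower, with control UMIs in 31 cells and 76.7% of them in 5 cells. Ccl17 was also a leading gene of the dendritic cell-like cluster, so dendritic cells within the macrophage class are not excluded. The type I interferon list had a median of 0.24 (0.09 to 0.30), or 0.10 with the stricter cell filter, and the interferon-gamma list -0.36 (-0.47 to -0.21). Ctsk, the bone-resorbing protease cathepsin K, was 178-fold higher in RT with 92.8% of its UMIs in 5 of 586 cells, and the neutrophil granule genes Camp and Ngp came from 1 cell.

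T cell-like cells of the RT library carried more cytotoxic and dividing-cell RNA. Naive cells numbered 667 of 1935 T cell-like cells in control and 116 of 1474 in RT. The gene folds and the proliferation median that follow include them. Gzmb, the killing protease granzyme B, was 2.49-fold higher at 466 CPM (449 to 484), Pdcd1, the inhibitory receptor PD-1, 2.35-fold, Ifng 1.78-fold and Mki67 2.51-fold. The cytotoxic list had a median of 0.80 (0.71 to 0.86), with 12 of 19 members at least 1.5-fold higher, and the proliferation list 0.94 (0.79 to 1.14). Without naive cells the cytotoxic median was 0.47 (0.37 to 0.54) over T cell-like cells and 0.24 (0.15 to 0.32) over CD8 T cell-like cells. The type I interferon list had a median of 0.48 (0.43 to 0.60) over all T cell-like cells and 0.45 without naive cells, with Isg15 2.18-fold and Ifit1 2.16-fold higher. In NK cell-like cells Isg15 was 2.12-fold lower, at 45.7 CPM (34.1 to 60.1) against 96.7 (70.6 to 129).

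Fibroblast-like cells showed fewer dividing-cell transcripts and more interferon transcripts after RT. All 31 measured proliferation genes were at least 1.5-fold lower, with a median of -1.56 (-1.74 to -1.38), and Ube2c, which drives exit from mitosis, was 5.99-fold lower. Cdkn1a was 3.92-fold higher at 338 CPM (314 to 362), and the p53 target list had a median of 0.36 (0.12 to 0.48), with 6 of 23 members at least 1.5-fold higher and 1 lower. The type I interferon list had a median of 0.81 (0.71 to 1.03), with 22 of 33 members at least 1.5-fold higher, and Ifit1 was 4.86-fold higher. The stress list was higher as well, with a median of 0.42 (0.38 to 0.55). Reg1, a secreted pancreatic protein, was 15.3-fold higher with 86.7% of its UMIs in 5 cells, and Il1rl1, the receptor for interleukin-33, was 22.8-fold lower with 71.7% of its control UMIs in 5 cells. These values rest on 129 control and 134 RT cells.

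**Figure D1:**
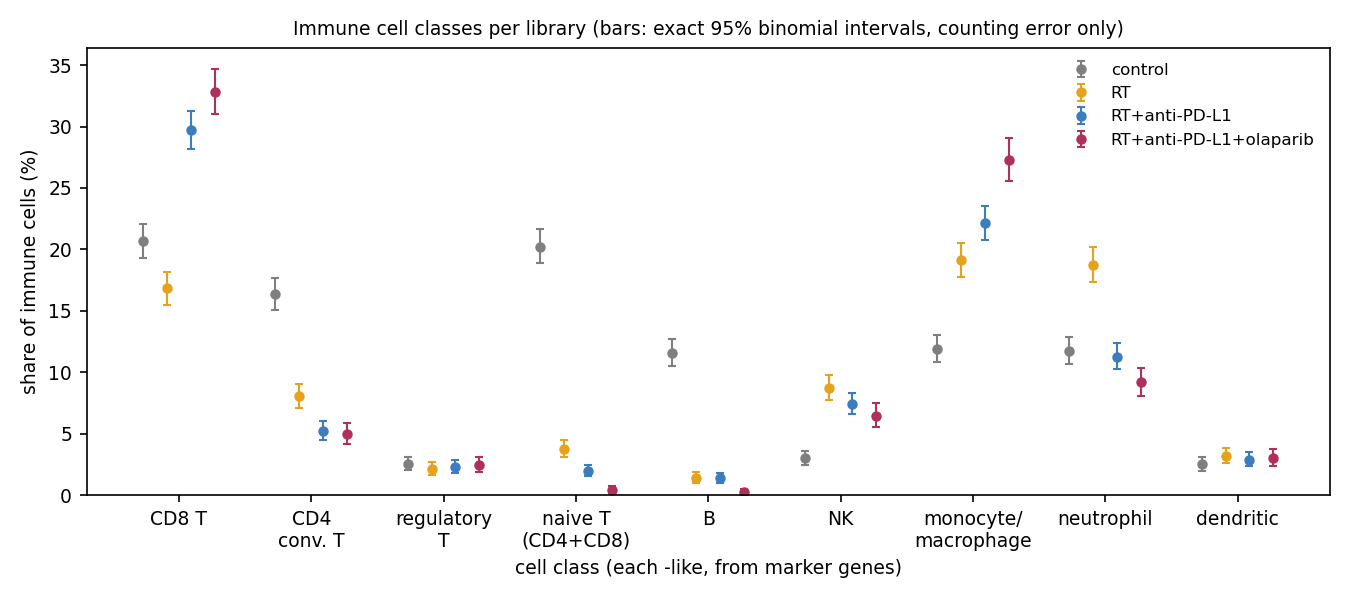
Share of immune cells (%, linear axis from 0) for 9 classes in the 4 libraries, with points for shares and bars for exact 95% binomial intervals of counting error. CD8 T cell-like cells reached 29.7% with RT+anti-PD-L1 and 32.8% in the combination, against 20.7% in control and 16.8% with RT.

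The comparison of RT+anti-PD-L1 with RT addressed what PD-L1 blockade adds. CD8 T cell-like cells made up 29.7% of immune cells (28.2 to 31.3) against 16.8% with RT, a log2 ratio of 0.82 (0.68 to 0.95). All T cell-like cells took 54.3% (52.7 to 56.0) against 48.1%. Conventional CD4 T cell-like cells were less frequent (5.24% against 8.05%), and regulatory T cell-like cells stood at 2.30% and 2.12%. Neutrophil-like cells were 1.66-fold less frequent (11.3%, 10.3 to 12.4, against 18.7%, 17.4 to 20.2). Among CD8 T cell-like cells without naive ones, the sub-cluster rich in Ccl4, Ccl3 and Xcl1 held 25.1% (22.4 to 27.9) against 16.7% (13.4 to 20.3).

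Interferon genes of both kinds were higher in tumour-like cells of the RT+anti-PD-L1 library. The type I list had a median log2 ratio of 0.40 (0.35 to 0.43), with 9 of 38 members at least 1.5-fold higher and 0 lower. Isg15 was 1.88-fold higher at 164 CPM (160 to 167), and Ifit1 1.53-fold. The interferon-gamma list had a median of 0.62 (0.59 to 0.67), with 15 of 22 members at least 1.5-fold higher, among them Gbp2, a guanylate-binding defence protein, at 1.60-fold. Cxcl10 was 1.90-fold and Cd274, which encodes PD-L1, 1.53-fold higher. MHC class I genes had a median of 0.35 (0.32 to 0.37). Csf2, the growth factor GM-CSF, was 4.54-fold higher at 16.3 CPM (15.2 to 17.4). The stress list moved the same way with a median of 0.38 (0.36 to 0.40), and matrix genes had a median of 0.54, with Col3a1 1.57-fold and Sparc 1.64-fold higher. Xist, a host RNA, moved with them in tumour-like cells, at 8.72 CPM (7.96 to 9.53) against 5.01 (4.36 to 5.73). Host RNA in these cells is therefore not excluded for matrix genes, nor for the interferon-gamma and MHC class I lists in this comparison. For the type I list the values argue against it as the main source. Xist in tumour-like cells stayed far below the 436 CPM or more of host classes. The summed list stood at 1572 CPM in tumour-like and 1992 CPM in immune cells of control, and at 2873 and 3779 CPM in the combination. The amount of host RNA was estimated only for the combination against control. A cluster marked by Grem1 and Col8a1 held 28.4% of tumour-like cells in this library and 19.4% in RT. Pcp4, a calmodulin regulator, stood at 9.39 CPM (8.60 to 10.2) against 0.0470 (0.00570 to 0.170) with RT, and Fam25c at 7.90 (7.18 to 8.68) against 0.0705 (0.0145 to 0.206). Fgb, a fibrinogen chain, was at least 57.3-fold higher. For all these 3 genes, 5 or fewer cells held 100% of the UMIs.

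Macrophages of this library had more MHC class II and interferon-gamma RNA than those of RT. H2-Ab1 was 1.78-fold and H2-Eb1 1.94-fold higher, and the class II list had a median of 0.65 (0.54 to 0.78). The interferon-gamma list had a median of 0.69 (0.58 to 0.83), and the inflammatory macrophage list 0.71 (0.54 to 0.83) with Il1b, a fever-causing cytokine, 2.03-fold higher. Ccl5, a chemokine that draws T cells, was 2.80-fold higher. It was also a leading gene of a CD8 T cell-like sub-cluster, and T cell RNA among macrophages was not estimated. Ly6i was 3.54-fold higher and spread over many cells, the top 5 holding 12.9% of its UMIs in the library where it was highest. The type I list had a median of 0.27 (0.20 to 0.36). Ifnb1, interferon-beta itself, stood at 0.194 CPM (0.00491 to 1.08) against 8.19 (5.40 to 11.9) with RT, from 1 and 27 UMIs. Neutrophil-like cells showed an interferon-gamma median of 1.04 (0.83 to 1.28) and a type I median of 0.55 (0.40 to 0.66). Dendritic cell-like cells went the other way for the type I list, at -0.27 (-0.41 to -0.15).

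T cell-like cells carried 1.52-fold more Gzmb, 1.55-fold more Pdcd1 and 1.39-fold more Ifng than with RT. The class differed in make-up, with 1032 CD8 T cell-like cells of 1888 against 516 of 1474, and among CD8 T cell-like cells without naive ones Gzmb was 1.35-fold and Ifng 1.07-fold higher, with a cytotoxic median of 0.21 (0.15 to 0.28). The cytotoxic list had a median of 0.50 (0.40 to 0.53), with 6 of 19 members at least 1.5-fold higher and 0 lower, and the inhibitory receptor list 0.39 (0.33 to 0.51). The type I interferon list had a median of 0.15 (0.07 to 0.22), which ran from 0.07 with doublets kept to 0.30 with each library clustered alone. Rgs16, a brake on chemokine receptor signals, was 2.33-fold higher, while Cd40lg, a helper signal for B cells, was 2.14-fold lower, beside a lower CD4 share. Fibroblast-like cells carried 6.16-fold more Cxcl10 and 2.84-fold more Cxcl9, and their chemokine list had a median fold of 2.84, with 7 of 9 members at least 1.5-fold higher. Matrix genes in these cells had a median of 0.60 (0.56 to 0.67).

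The combination against RT+anti-PD-L1 addressed what olaparib, by the sample labels, adds. The CD8 T cell-like share was 32.8% (31.0 to 34.7) against 29.7%, a log2 ratio of 0.14 (0.04 to 0.25), which was -0.01 when CD8 cells were counted by their own UMIs and 0.45 with each library clustered alone. T cell-like cells as a whole stood at 53.2% (51.3 to 55.1) against 54.3%, not told apart by counting error. The make-up of the CD8 class differed more, since the sub-cluster rich in Prf1, Pdcd1, Havcr2 and Gzmb held 40.7% (37.3 to 44.1) of the CD8 T cell-like cells without naive ones, against 24.6%. Monocyte or macrophage-like cells were 1.23-fold more frequent (27.3% against 22.1%), and B cell-like cells numbered 7 of 2592 immune cells against 48 of 3474. Among non-immune cells, tumour-like cells took 95.5% (94.7 to 96.3) against 85.7% (84.0 to 87.2), and fibroblast-like cells 3.06% (2.42 to 3.82) against 11.3% (9.91 to 12.8).

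In tumour-like cells the type I interferon list had a median log2 ratio of 0.38 (0.35 to 0.43), with 10 of 38 members at least 1.5-fold higher and 0 lower. Ifit1 stood at 71.9 CPM (70.1 to 73.8) against 48.1. Zbp1, a sensor of nucleic acid in the cell, was 1.28-fold higher and Isg15 1.08-fold. Cxcl10 was 1.37-fold higher, whereas the interferon-gamma list had a median of 0.17 (0.09 to 0.19), with 0 of 22 members 1.5-fold apart, and Cd274 differed by 1.03-fold. Proliferation genes had a median of 0.36 (0.33 to 0.38), with Cenpf, a centromere protein, 1.44-fold and Mki67 1.23-fold higher. A cluster led by Anln and Cenpf held 26.1% of tumour-like cells in the combination and 18.4% in RT+anti-PD-L1. The p53 target list was lower, at -0.19 (-0.24 to -0.15), and the matrix list at -0.34 (-0.42 to -0.23), with Col3a1 1.65-fold lower. Host Xist in tumour-like cells was lower with them, at 3.26 CPM (2.88 to 3.67) against 8.72, as was the fibroblast-like share. Parp1, a target of olaparib, differed by 1.04-fold. DNA repair genes had a median of 0.06 (-0.00 to 0.11). Tnnc2, Myoz1 and Pgam2, genes of skeletal muscle, were 36.0-fold, 43.8-fold and 27.7-fold lower, and 100% of their UMIs in the RT+anti-PD-L1 library came from 5 or fewer cells. Summed muscle RNA stood at 90.5 CPM in that library and at 5.41 to 6.34 in the others.

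Macrophages of the combination and of RT+anti-PD-L1 were close in the type I list, at a median of 0.19 (0.12 to 0.24), and in MHC class I, at 0.00 (-0.04 to 0.04). Arg1, which depletes arginine, was 1.54-fold higher, and Gdf15, a stress cytokine, 2.80-fold lower, with 45.9% of its RT+anti-PD-L1 UMIs in 5 cells. T cell-like cells carried 1.52-fold more Gzmb, at 1075 CPM (1051 to 1099), with Pdcd1 1.61-fold and Ifng 1.75-fold higher. These folds cover the whole class, which differed in make-up, with 851 CD8 T cell-like cells of 1379 against 1032 of 1888. The naive and memory list had a median of -0.72 (-0.79 to -0.66), with 9 of 12 members at least 1.5-fold lower, and stood at -0.75 (-0.93 to -0.55) among CD8 T cell-like cells without naive ones. Tcf7, a factor of memory-like T cells, was 1.68-fold lower in all T cell-like cells, and Myb 2.38-fold lower. Ccl1, a chemokine, and Gzmf were 2.97-fold and 2.65-fold higher, with 60.1% and 87.5% of their UMIs in 5 cells. Fibroblast-like cells numbered 75 in the combination. Their proliferation list stood at -1.04 (-1.32 to -0.75) and their inflammatory list at -0.70 (-0.78 to -0.66), beside a stress list at -0.48 (-0.59 to -0.43). Actg2, a smooth muscle actin, was 4.24-fold higher, with 73.3% of its UMIs in 5 cells.

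**Figure D2:**
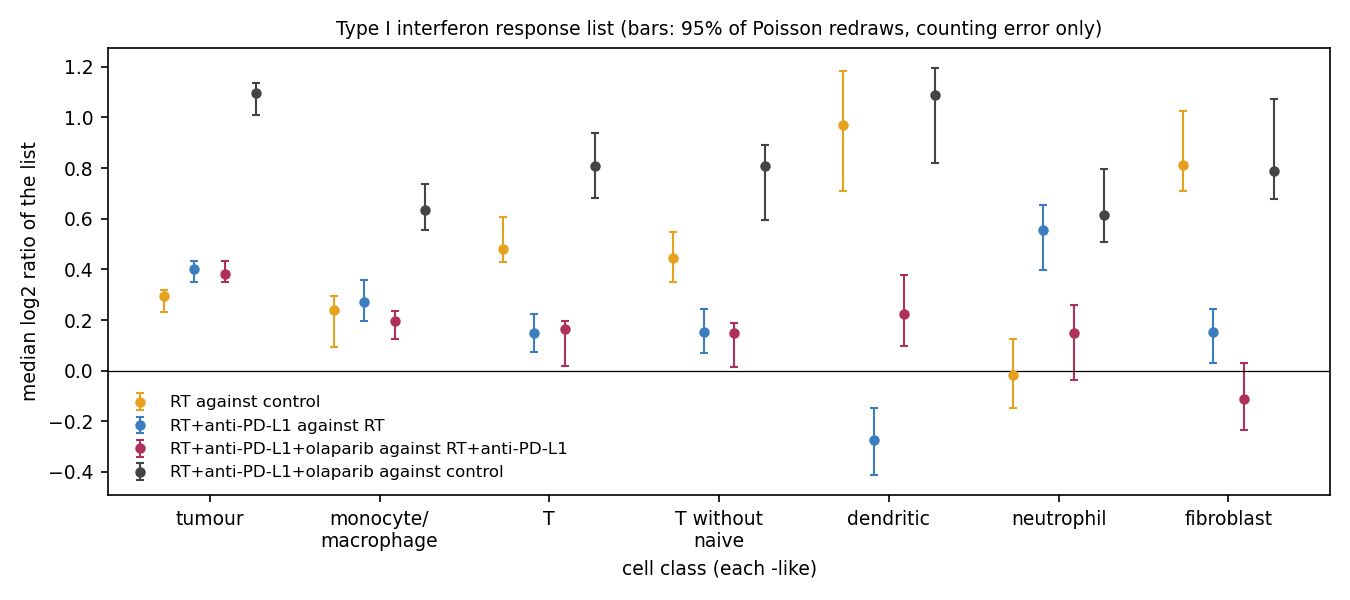
Median log2 ratio of the type I interferon response list (linear axis) by cell class, with 1 point per comparison and bars for 95% of Poisson redraws of the counts. In tumour-like cells the median was 1.10 for the combination against control and 0.30, 0.40 and 0.38 for the other comparisons in the order of the legend.

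Against control, the combination library summed the differences of the whole treatment. CD8 T cell-like cells made up 32.8% of immune cells against 20.7%, a log2 ratio of 0.67 (0.54 to 0.79), and 32.9% against 16.0% once B cell-like and naive T cells were left out (log2 ratio 1.04). Other choices gave log2 ratios from 0.38 at Leiden resolution 2 to 1.62 with doublets kept. The class leaves out an unnamed sub-cluster with Cd8a in 38.0% of its cells, 414 cells in control and 147 in the combination. It also leaves out another with Cd8a in 39.8%, 64 and 91 cells, so the size of the rise depends on the CD8 rule. T cell-like cells as a whole were slightly less frequent, with a log2 ratio of -0.14 (-0.21 to -0.08). Monocyte or macrophage-like cells were 2.29-fold more frequent, NK cell-like cells 2.15-fold (1.57-fold and 1.48-fold without B cell-like and naive T cells), B cell-like cells 40.0-fold less (7 against 381 cells), and naive T cell-like sub-clusters took 0.424% (0.212 to 0.758) against 20.2%. Haemoglobin RNA stood at 0.897 CPM over the whole library against 172 in control, with 736 in RT and 643 in RT+anti-PD-L1.

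The type I interferon list in tumour-like cells had a median log2 ratio of 1.10 (1.01 to 1.14), or 2.14-fold, with 32 of 38 members at least 1.5-fold higher and 0 lower. Isg15 (ENSMUSG00000035692, chromosome 4, from 156199424 to 156200818 on mm10) was 2.27-fold higher at 177 CPM (174 to 180). Ifit1 (ENSMUSG00000034459, chromosome 19, from 34640871 to 34650009) was 2.33-fold higher and Zbp1 2.26-fold. Cxcl10 (ENSMUSG00000034855, chromosome 5, from 92346638 to 92348889) was 3.65-fold higher at 504 CPM (500 to 509), and Cxcl9 2.10-fold. The interferon-gamma list had a median of 0.95 (0.89 to 0.97), with 18 of 22 members at least 1.5-fold higher, and the chemokine list 1.15 (1.06 to 1.22). Cd274 stood at 27.6 CPM (26.5 to 28.8) against 14.1. H2-K1 was 1.10-fold higher, and MHC class I had a median of 0.36 (0.32 to 0.38). Genes of cytosolic nucleic acid sensing, the route from stray DNA or RNA to interferon, had a median of 0.16 (0.09 to 0.26), with Tmem173, which encodes STING, 1.25-fold higher. The proliferation list had a median of 0.15 (0.13 to 0.19) and the p53 target list 0.03 (-0.03 to 0.08). The dissociation stress list was higher too, with a median of 0.55 (0.53 to 0.56) and 10 of 21 members at least 1.5-fold higher. The largest tumour-like cluster was one led by Dmbt1 in control (38.6%, against 21.2% in the combination) and the one led by Anln and Cenpf in the combination (26.1%, against 23.3%). With 5 CPM added to each level, the type I median was 0.75.

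**Figure D3:**
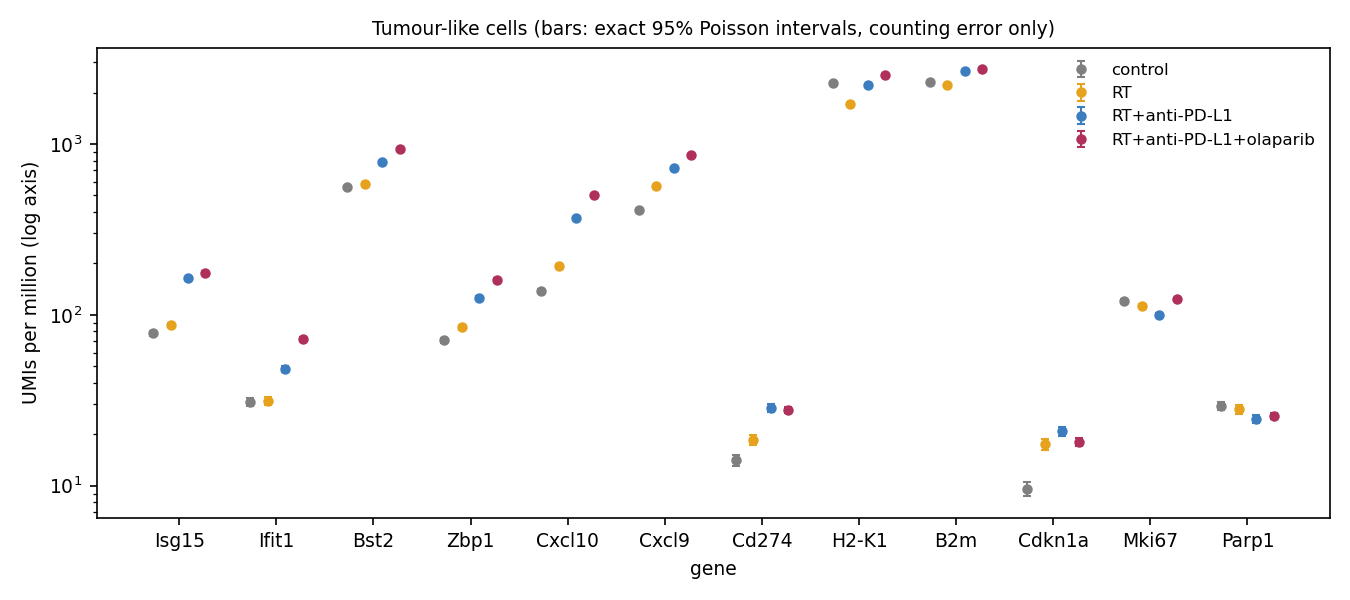
Level in CPM (log axis) of 12 genes in tumour-like cells of the 4 libraries, with bars for exact 95% Poisson intervals of counting error. Cxcl10 stood at 138 in control, 194 with RT, 368 with RT+anti-PD-L1 and 504 in the combination, while Parp1 stayed between 24.6 and 29.4.

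Most other classes measured carried more type I interferon RNA as well, but in NK cell-like cells Isg15 stood at 76.5 CPM in the combination and 96.7 (70.6 to 129) in control, not told apart by counting error. The list median was 0.63 (0.55 to 0.74) in macrophages, with 21 of 38 members at least 1.5-fold higher, and 0.81 (0.68 to 0.94) in T cell-like cells, with 23 of 38. It was 0.79 (0.68 to 1.07) in fibroblast-like cells, 0.61 (0.51 to 0.80) in neutrophil-like cells and 1.09 (0.82 to 1.19) in dendritic cell-like cells. Each of these medians, like that in tumour-like cells, lay at percentile 100 of 10000 random lists matched on expression, which describes the genes of these libraries and not a spread between animals. In fibroblast-like cells Ifit3 was 14.9-fold higher, with 91.0% of its combination UMIs in 5 cells, and Ifit1 8.21-fold higher. Interferon-beta RNA itself was not higher, since Ifnb1 in macrophages stood at 0.501 CPM (0.0606 to 1.81) in the combination and 6.94 (3.79 to 11.6) in control, from 2 and 14 UMIs.

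T cell-like cells of the combination carried 5.75-fold more Gzmb (ENSMUSG00000015437, chromosome 14, from 56258838 to 56262260), 5.86-fold more Pdcd1 and 4.32-fold more Ifng than those of control, and Tcf7 was 3.68-fold lower. The cytotoxic list had a median of 1.60 (1.39 to 1.65), with 17 of 19 members at least 1.5-fold higher, the inhibitory receptor list 1.23 (1.16 to 1.43), and the naive and memory list -1.80 (-1.91 to -1.69). Among CD8 T cell-like cells without naive ones these medians were 0.56 (0.48 to 0.62), 0.58 (0.45 to 0.75) and -1.03 (-1.28 to -0.75), and the largest sub-cluster was the Gzmk-rich one in control (61.3%) and the Prf1-rich one in the combination (40.7%). Naive cells made up 47.4% of that class in control and 0.588% in the combination. Gzmf was at least 116-fold higher in T cell-like cells, from 0 UMIs in control. Macrophages carried 4.68-fold more Ccl5 and 3.62-fold more Ly6i. T cell RNA is not excluded for Ccl5 here either. Retnla was 6.33-fold and Plet1 29.5-fold lower, and 5 control cells held 85.6% of the Plet1 UMIs. MHC class II genes in macrophages had a median of -0.18 (-0.34 to -0.14) and changed sign to 0.02 when each cell weighed the same. Fibroblast-like cells had a proliferation median of -2.15 (-2.38 to -1.86), with all 31 members at least 1.5-fold lower, and a p53 target median of 0.63 (0.49 to 0.89) with Cdkn1a 3.51-fold higher.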

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

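Proliferation genes went opposite ways in 2 classes of the RT library against control, with a median log2 ratio of 0.94 in T cell-like and -1.56 in fibroblast-like cells, 2.50 apart, and the cause was not tested. The same list stood at 1.45 in T cell-like and -2.15 in fibroblast-like cells of the combination against control, 3.60 apart, which was not tested further. The T cell-like values include the naive sub-clusters, frequent in control, where 0.642% and 0.758% of cells had Mki67. Neutrophil chemoattractant genes were higher in tumour-like cells of RT against control (0.76) and lower in fibroblast-like cells (-0.64), 1.40 apart, also not tested, and the fibroblast-like value turned to 0.13 as a mean over cells.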

How the results depend on the processing

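Of 160 alternatives to the 20 main results, 156 kept the sign and 4 changed it, and 1985 alternatives to 270 other results were run; the cause was not tested for any of them. No paired analysis was possible because each group is 1 pooled library. With each library clustered alone, 0 NK cell-like clusters were named in control, so some results had no value. There the share of T cell-like cells among immune cells, RT against control, had a log2 ratio of -0.36, RT+anti-PD-L1 against RT 0.34, and RT+anti-PD-L1+olaparib against RT+anti-PD-L1 -0.15. The share of CD8 T cell-like cells among immune cells was -0.63 for RT against control, 0.61 for RT+anti-PD-L1 against RT, 0.45 for the combination against RT+anti-PD-L1 and 0.43 for the combination against control. The share of unnamed T cell-like cells turned to 0.50 for RT+anti-PD-L1 against RT. The type I interferon response list in monocyte or macrophage-like cells, RT against control, was 0.30 (but 0.10 with the stricter cell filter), and in T cell-like cells 0.30 for RT+anti-PD-L1 against RT and, turned, -0.0352 for the combination against RT+anti-PD-L1. The proliferation list in monocyte or macrophage-like cells turned to -0.15 for the combination against control. By UMIs per cell, the T cell-like share was -0.11 and the CD8 share turned to -0.0104 for the combination against RT+anti-PD-L1, with CD8 at 0.40 against control. With doublets kept, the CD8 share turned to 0.54 for RT against control and was 1.62 for the combination against control. The type I list in T cell-like cells was then 0.68 for RT against control, 0.0712 for RT+anti-PD-L1 against RT and 0.97 for the combination against control. Also for the combination against control, the interferon-gamma response list in dendritic cell-like cells turned to -0.40, their T cell-recruiting chemokines list to -0.21, and the dissociation stress list in neutrophil-like cells to 0.0218. Without B cell-like and naive T cells, the CD8 share turned to 0.0479 for RT against control and was 1.04 for the combination against control. With the stricter cell filter, CD8 was 0.64 for RT+anti-PD-L1 against RT and 0.49 for the combination against control, and at Leiden resolution 2 it was 0.58 and 0.38. With 5 CPM added, the type I interferon response list in tumour-like cells was 0.19, 0.30, 0.31 and 0.75 in the order of comparisons used above, and in T cell-like cells 0.40 for RT against control and 0.60 for the combination against control. By median-ratio scaling it was 0.40 in T cell-like cells for RT against control and 0.22 for the combination against RT+anti-PD-L1. As a mean over cells, it was 0.44 in tumour-like cells for RT+anti-PD-L1 against RT, and in T cell-like cells 0.26 for the combination against RT+anti-PD-L1 and 0.98 against control. The mean over cells turned these: for RT against control, neutrophil chemoattractants list in fibroblast-like cells 0.13, dissociation stress list in monocyte or macrophage-like cells 0.0669 and X inactivation list in tumour-like cells -0.0108. For RT+anti-PD-L1 against RT, it turned the type I list in fibroblast-like cells to -0.0583, the result for the neutrophil chemoattractants list in fibroblast-like cells, RT+anti-PD-L1 against RT, to -0.0254, their Y-linked list to -0.15, and the macrophage stress list to -0.0337. It turned the p53 targets list in endothelial-like cells, RT+anti-PD-L1+olaparib against RT+anti-PD-L1, to -0.0302 and the T cell-recruiting chemokines list in fibroblast-like cells, RT+anti-PD-L1+olaparib against RT+anti-PD-L1, to 0.0630. In the same comparison the proliferation list in macrophages turned to 0.0267. It turned the MHC class II presentation list in monocyte or macrophage-like cells, RT+anti-PD-L1+olaparib against control, to 0.0177, and the dissociation stress list in monocyte or macrophage-like cells, RT+anti-PD-L1+olaparib against control, to -0.000867. In the same comparison their immunosuppressive list turned to 0.0494. With members with at least 100 UMIs, the proliferation list in monocyte or macrophage-like cells, RT against control, turned to 0.0550, and the immunosuppressive list to 0.20 for the combination against control. With members with at least 1 UMI, the T cell-recruiting chemokines list in dendritic cell-like cells turned to 0.51 for the combination against RT+anti-PD-L1 and to -0.0723 against control, and the Y-linked list in fibroblast-like cells turned to 0.18 for the combination against RT+anti-PD-L1.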

Other observations

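In tumour-like cells, neutrophil chemoattractants were higher in RT against control, with a median log2 ratio of 0.76 (0.47 to 0.92), and Cxcl2, which draws neutrophils, was 1.99-fold higher. In RT+anti-PD-L1 against RT their median was 0.93 (0.58 to 1.18), while neutrophil-like cells were less frequent there. Epithelial to mesenchymal transition genes had a median of 0.28 (0.21 to 0.34) in RT+anti-PD-L1 against RT, and hypoxia genes -0.22 (-0.28 to -0.19) in the combination against control. Immunosuppressive macrophage genes stood at -0.37 (-0.48 to -0.20) in RT against control. Inflammatory fibroblast genes stood at 0.60 (0.41 to 0.66) in the same comparison. The Y-linked list in tumour-like cells stood at -0.12 (-0.18 to -0.06) in the combination against control.

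Endothelial-like cells split into a vessel cluster, led by Gpihbp1 and Emcn, and a lymphatic cluster, led by Ccl21a and Lyve1. The lymphatic cluster held 62.1% of them in control, 48.6% with RT, 14 of 56 cells with RT+anti-PD-L1 and 5.88% in the combination, there 2 of 34 cells. T cell-like cells that no subset rule named numbered 594 of 3297 immune cells in control and made up 19.5% with RT, 15.7% with RT+anti-PD-L1 and 11.7% in the combination. A CD8 T cell-like sub-cluster needed Cd8a in 50% of its cells. An unnamed one of 1162 cells had Cd8a in 38.0% and Cd4 in 1.55%, with 414, 306, 295 and 147 cells in the same order of libraries. Another of 402 cells had Cd8a in 39.8% and Cd4 in 1.99%, with 64, 116, 131 and 91 cells. A further 118 unnamed cells formed a sub-cluster led by the myeloid genes S100a8, S100a9 and Il1b, with the T cell gene Cd3e in 73.7% of them, so their class is uncertain. No cluster was named plasma cell, which does not bound their share.

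Of the tests on resting lymphocytes, the one on loss of all lymphocytes alike was chosen after the result was seen, as was the share without B cell-like and naive T cells. B cell-like and naive T cell-like cells were frequent only in control, which may reflect loss after radiation or lymph node tissue taken with the control tumours. NK cell-like cells made up 31.4% of NK and macrophage-like cells together in RT (28.3 to 34.6) and 20.1% in control (16.7 to 23.9). At 25.1% with RT+anti-PD-L1 and 19.2% in the combination they were not clearly lower than control. On day 5 they were thus not reduced alongside B cell-like and naive T cells. The ratio cannot tell NK cells that were spared from NK cells lost and replaced, so it does not decide on a loss of all lymphocytes alike. Lymph node stroma genes, mostly Ccl19, stood at 138 CPM in host stromal cells of control (126 to 152) and at 147 with RT, 148 with RT+anti-PD-L1 and 85.8 in the combination. Members differed, since in the same order Ccl19 had 438, 496, 684 and 104 UMIs and Glycam1 14, 20, 5 and 68. Node tissue was therefore neither shown nor excluded. Whether these cells came from blood, node or tumour stays open.

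Of the tests on the interferon genes of tumour-like cells, the one on Xist and the values without the cluster of few UMIs were chosen after the result was seen. The type I list was higher in the combination than in control within 5 of 5 clusters used, with a mean median of 1.13 (lowest 0.69, highest 1.43), which argues against a shift between clusters. Xist, a host RNA, was lower in these cells with a log2 ratio of -0.29 (-0.56 to -0.02), and free RNA of immune cells could account for 0.582% of the difference (0.536 to 0.633), so host RNA leaking into tumour droplets does not account for it. The tumour-like cells may respond to interferon-gamma from T cells, since that list stood at 0.95, or to type I interferon from themselves or from host cells. Ifnb1 had 3 UMIs in the whole combination library, all in macrophages and NK cell-like cells, against 14 in control. No Ifnb1 RNA was thus seen in tumour-like cells of the combination, but counts so near the floor do not settle the source. The values do not separate these sources, nor the olaparib step from a difference between pools of tumours.

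The tests on p53 targets were devised once the list values were known, the vessel cluster test last, and each had its prediction written before it was run. The list was higher in endothelial-like cells of RT (0.47, 0.22 to 0.76) and of the combination (0.93, 0.73 to 1.37) against control, where Cdkn1a was 2.05-fold and 3.92-fold higher, but not in tumour-like cells (0.05 and 0.03), although Cdkn1a itself was 1.84-fold and 1.89-fold higher there. Endothelial-like members differed in RT, with Ccng1 3.11-fold and Btg2 1.98-fold higher but Mdm2 1.28-fold and Pmaip1 1.76-fold lower, the last 2 with overlapping intervals. In the vessel cluster 6 of 12 measured members were at least 1.5-fold higher in RT and 1 lower. For the combination these were 9 of 12 and 0. With tumour-like counts thinned to the same depth, 0.6% of draws reached the endothelial-like median for RT and 0% for the combination. This argues against error in counting UMIs only. Thinning acted on pooled counts, so it did not cover variation between cells and cannot exclude chance among few cells. Endothelial-like cells numbered 66 in control, 72 in RT and 34 in the combination, the last below the minimum set for a class. Within the vessel cluster the median was 1.30 (0.88 to 1.52) for the combination, from 32 and 25 cells. That value argues against a shift between clusters. Impaired p53 function in the tumour line may explain the gap, but in control the list stood at -0.57 in tumour-like against endothelial-like cells, at percentile 14.0 of random lists, which leaves it open. Sequencing of Trp53 in the line would tell.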
